A study of Homo sapiens with 6 samples.

How the data were processed

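The series holds 6 single-colour bead arrays of human PC3 cells in 3 groups of 2, transfected for 48 h with a control siRNA, a DAB2IP siRNA or a miR-149-3p mimic. Per the labels' protocols, total RNA was extracted with QIAzol, 2 µg were reverse transcribed, amplified and transcribed into cRNA, and the signal was read with Cy3-streptavidin. Groups and replicate numbers were taken from the sample titles. The titles of the control samples say control without naming an siRNA, and their descriptions call them siC.

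The authors deposited a table of unnormalized intensity values, 1 per probe and array, with no background subtraction, exported with GSGX 1.9.0 per the file headers. A second deposited table holds the intensity values after cubic spline normalization, also without background subtraction per the file headers. Both tables give a detection p-value per probe and array, deposited by the authors, and these differ by at most 0.0013 between the tables. The authors also deposited the values of the series matrix, which are in log2 units. Each of its columns correlated with log2 of the unnormalized intensities of the same array at 0.999 or above (0.9991 to 0.9999) and with other arrays at 0.9933 or below, and all columns had a median of 7.27, so it was read as single-channel log2 levels that are not centred. What was done to make them is not given in the sources used here. The submitters' processing notes name GenomeStudio and R 3.2.2, with no role. It holds 784 rows without values, which were left out.

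Of 47323 probes with values, 93 control rows (92 of them spike-in probes, of which 0 to 5 per array were detected) took no part in the tests. Gene symbols were updated through the gene ID for 35672 probes and through the accession for 84, with an NCBI gene table of the GRCh38.p14 assembly that was used for names only. The symbol in the file was kept for 8204 probes, and 3270 probes have no gene name. The median unnormalized intensity was 170.2 and 146.1 on the control arrays, 143.8 and 157.2 on the DAB2IP siRNA arrays and 149.0 and 157.6 on the mimic arrays. In the unnormalized table, 2 intensities were below 0.

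All choices here were made before the data were examined, unless said otherwise. The unnormalized intensities were normalized with the neqc function of limma 3.58.1 in R 4.3.3 (normexp background correction from the detection p-values, offset 16, quantile normalization, log2). Probes detected at a detection p under 0.05 on both arrays of at least 1 group were kept, and the probe with the highest mean over the 6 arrays stood for its gene, which left 15767 genes. A single limma fit (lmFit and eBayes, two-sided) over the 6 arrays, with 3 residual degrees of freedom and a prior of 3.25, gave 3 comparisons: DAB2IP siRNA against control, mimic against control, and mimic against DAB2IP siRNA. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values of single genes are from this fit. Fold changes are on the log2 scale of the background-corrected values, treated minus reference. Where a probe was not above background on any array of a group, the fold change is given as a bound: the mean of the brighter group against the mean, per array of the dimmer group, of the higher of the lowest level among detected probes and the probe's own level.

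Named genes are, per comparison, the 12 with the largest rise and the 12 with the largest fall among called genes whose treated arrays both lie outside the range of both reference arrays, leaving out symbols of uncharacterised genes, pseudogenes, Y-linked genes and XIST. For the comparison of the treatments, the 6 largest each way were taken. DAB2IP and up to 4 called members of each gene list with the largest change (or up to 2 where none was called) were added, and up to 10 genes called in both comparisons in the same direction. Some genes that meet the rule are not reported here. Any gene outside this rule is said to have been chosen after its values were seen, except list members that account for a count.

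The 31 gene lists hold 453 genes, of which 1 was not matched. They cover NF-kB and inflammatory targets, RAS-ERK output, mesenchymal and epithelial genes, FOXO, Wnt, p53, YAP, TGF-beta and NRF2 targets, G1/S and DNA replication, mitosis, interferon-stimulated genes, cholesterol synthesis, the ATF4 and amino acid response, ER chaperones, hypoxia and glycolysis, the BCL2 family, extracellular proteases, the RasGAP family, small RNA machinery, reported miR-149-3p targets and heat shock genes. Others track RNA quality (ribosomal proteins, respiratory chain, immediate early genes) or other cell types (leukocyte, fibroblast, endothelial, luminal prostate and neuroendocrine markers). The 27 lists with at least 5 tested genes were tested with camera at the preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27. They were tested again with an estimated correlation, where the test rests on the 3 residual degrees of freedom, and with fry, which tests whether a list moves on balance 1 way without comparing it with other genes.

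Both treatments share the control arrays, so the correlation and covariance of fold changes were set beside 1000 simulations of unchanged groups against the same controls, and shared calls beside the overlap of independent lists. A split of the control arrays between the treatments was added after the data were seen. The fit was tested on simulated data with 200 changed genes among 15767, fewer than were called in any comparison of the data. The noise was drawn from the variances that the fit had estimated. The rates of this test therefore need not hold for the data. For DAB2IP siRNA against control, the fit called 3.0%, 82.1% and 100% of genes changed by 0.5, 1 and 2 log2 units, with 6 false calls. For mimic against control it called 6.0%, 79.1% and 93.9%, with 11 false calls, and for mimic against siRNA 4.5%, 67.2% and 97.0%, with 7 false calls.

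The alternatives were the cubic spline table, quantile normalization without background correction, the series matrix, median centring alone, an offset of 50, no filter on detection, detection p under 0.01 on all 6 arrays, every detected probe on its own, the replicate number as a block, fits of only the 2 groups compared, eBayes with trend and robust, an adjusted p under 0.01, an added 1.5-fold threshold, the other set tests, and leaving out each array in turn. Values under 16 were set to 16 before log2 in the tables without background correction. Families of genes and the search of probes for the microRNA's site, in the last part, were chosen after the fold changes were seen. A test of that site over 3′ untranslated regions, which was planned, needs their sequence and was not analysed here. The slide as a block was not run, since the files used here do not give slides. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.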

Results

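Gene expression was measured on Illumina bead arrays in PC3 cells, a human prostate cancer cell line, 48 h after transfection. The 3 groups were a control small interfering RNA (siRNA), an siRNA against DAB2IP, and a synthetic mimic of the microRNA miR-149-3p, with 2 arrays each. The series sets the effects of the overexpressed microRNA beside those of losing DAB2IP, a RAS GTPase-activating protein that also acts as a scaffold in signalling. The labels do not say whether the 2 arrays of a group come from separate cultures, so the p-values measure the spread between these samples, which may be technical. Between 45.5% and 48.1% of the probes were detected on each array. The number of arrays limits the precision: the median standard error (SE) of a log2 fold change was 0.151. After normalization, the correlation across genes between the 2 arrays of a group was 0.994 for the control, 0.992 for the DAB2IP siRNA and 0.990 for the mimic, and it lay between 0.962 and 0.982 for arrays of different groups. On a multidimensional scaling plot, the first axis (53.6% of the variance) set the mimic arrays apart from the others, and the second (24.5%) set the DAB2IP siRNA arrays apart from the controls.

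DAB2IP itself was lower with both treatments. It was read by the probe ILMN_1783161, at positions 123587233 to 123587282 of chromosome 9 as the files give them. Their genome build is not given in the sources used here, and what the annotation places at these positions was not looked up. The level was 6.62 ± 0.01 log2 units in the control, 5.39 ± 0.37 with the DAB2IP siRNA and 5.62 ± 0.36 with the mimic (mean ± SD, n = 2 arrays each). The probe was not above background on either siRNA array, so DAB2IP was at least 1.84-fold lower there on the background-corrected scale (limma adjusted p = 0.0281). With the mimic it was above background on 1 of 2 arrays, with a log2 fold change of −1.01 (SE 0.233, limma adjusted p = 0.0221). With levels this near background, no fold between the 2 treatments is given. The other 2 DAB2IP probes were not detected on any array. The fitted log2 change depends on the background correction: without it, the values were −0.53 for the siRNA (−1.23 with it) and −0.42 for the mimic. The siRNA call was lost without a filter on detection and in each fit without a control or an siRNA array (adjusted p from 0.00292 to 0.142 over all alternatives). The mimic call was lost without either control array and without mimic replicate 1 (adjusted p from 0.00425 to 0.0989).

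**Figure D1:**
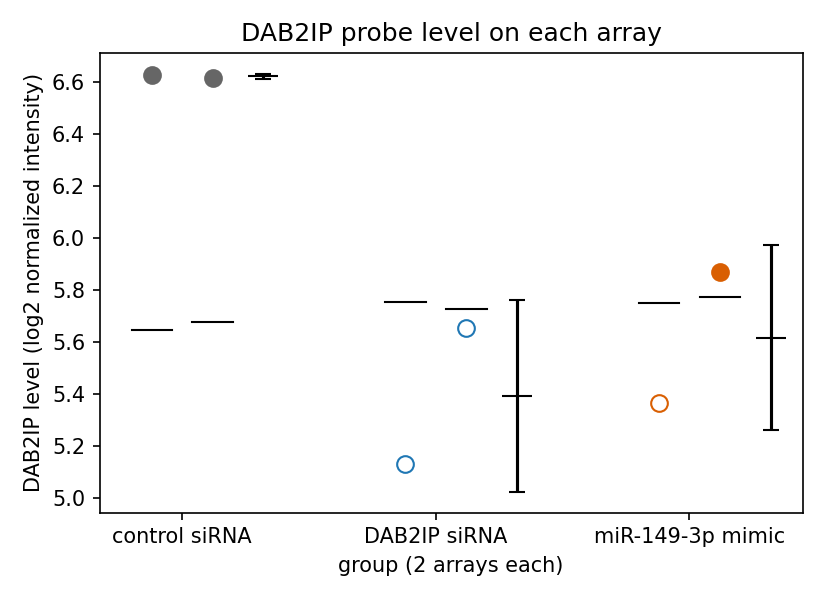
Level of the DAB2IP probe (log2 normalized intensity, vertical axis) on each of the 2 arrays of the 3 groups. Filled points passed the detection threshold and open points did not, the short lines give the lowest level among detected probes on that array, and the crossbars give the mean ± SD. The control arrays lie at 6.63 and 6.62, and the arrays of both treatments at or below 5.87.

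The comparison of DAB2IP siRNA with control asks what this siRNA does to gene expression in PC3 cells. The series holds no other group with an siRNA against DAB2IP and no rescue group. Effects of losing DAB2IP are therefore not separated from other effects of the siRNA. The tight junction gene CLDN1 rose most (log2 fold change 2.88, SE 0.136, limma adjusted p = 0.00235), followed by DDIT3, a transcription factor of the integrated stress response (2.62, SE 0.408, adjusted p = 0.018), and HERPUD1, which acts in the breakdown of misfolded endoplasmic reticulum (ER) proteins (2.35, SE 0.355, adjusted p = 0.0167). The cytokine gene IL11 fell most (−3.28, SE 0.216, adjusted p = 0.00384), followed by TRIB2, a pseudokinase (−2.57), and RRM2, a subunit of ribonucleotide reductase (−2.49). Other large rises were those of CFDP1 (2.21), the decoy receptor TNFRSF11B (2.20), the oxidized LDL receptor OLR1 (2.09), CHAC1 (1.98), LURAP1L (1.98), the amino acid transporter SLC16A10 (1.79), SESN2 (1.78), the cytokine gene IL24 (1.77) and ERVMER34-1 (1.76). Other large falls were those of GIPC1 (−2.38), the mevalonate pathway enzyme PMVK (−2.34), TXNIP (−2.31), smooth muscle actin ACTA2 (−2.24), caveolin CAV1 (−2.17), the kinase HIPK2 (−2.08) and the epithelial sodium channel subunit SCNN1G (−1.94). In all, 1777 of 15767 genes changed (730 higher and 1047 lower, 11.3%), of which 153 rose and 323 fell by at least 2-fold.

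Genes of the amino acid stress response rose with the DAB2IP siRNA. In the list of ATF4 and amino acid response genes, 10 of 16 rose and 0 fell, with DDIT3 (2.62), CHAC1 (1.98), SESN2 (1.78) and the cystine transporter SLC7A11 (1.39) in front. Adjusted over the list alone, 12 rose. The list rose against all other genes (camera adjusted p = 1.5e-06), with an adjusted p = 0.514 with an estimated correlation. ER chaperones and related genes also moved up (3 of 13 rose and 0 fell, 5 and 0 adjusted over the list alone), led by HERPUD1 (2.35), XBP1 (0.93) and SDF2L1 (0.84). Camera gave an adjusted p of 0.0121, and it was 0.657 with an estimated correlation. The call for this list rested on 1 array, since it was lost without DAB2IP siRNA replicate 1. The list mean lay 0.831 above the control mean on that array and 0.261 above it on replicate 2, so the direction was shared. Over the alternatives that keep all arrays, the camera adjusted p was 0.00061 to 0.0194.

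The cell cycle groups moved apart with the DAB2IP siRNA. Of the G1/S and DNA replication genes, 8 of 22 fell and 0 rose (11 and 0 adjusted over the list alone), among them RRM2 (−2.49), the replication factor GINS2 (−1.86), E2F2 (−1.25) and the licensing factor CDT1 (−0.81). For the list, the camera adjusted p was 2.23e-05 (adjusted p = 0.514 with an estimated correlation). Of the mitosis genes, 4 of 20 rose and 0 fell (TPX2 0.67, CCNA2 0.67, CCNB2 0.55, HMMR 0.53), with 10 higher and 1 lower adjusted over the list alone. Their camera adjusted p was 0.00304 (adjusted p = 0.514 with an estimated correlation).

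Among NF-kB and inflammatory targets, 7 of 24 rose and 1 fell with the DAB2IP siRNA (10 and 1 adjusted over the list alone). The chemokines CXCL2 (1.19) and CCL20 (0.90), the cytokine IL6 (0.93) and the feedback inhibitor TNFAIP3 (0.82) were the largest, and IL1B was the gene that fell (−0.79). Against all other genes, camera gave adjusted p = 0.00497 (adjusted p = 0.514 with an estimated correlation). Of the hypoxia and glycolysis genes, 6 of 20 fell and 0 rose (9 and 0 adjusted over the list alone), including PFKFB4 (−0.80), NDRG1 (−0.73), ANKRD37 (−0.73) and adrenomedullin ADM (−0.72). The camera adjusted p was 6.61e-04 (adjusted p = 0.514 with an estimated correlation). None of the other lists passed the test with this siRNA. Among them, the YAP targets came nearest (5 of 12 rose and 1 fell, adjusted p = 0.0699), with ANKRD1 (1.70), TGFB2 (1.28), the matricellular protein gene CCN1 (1.18) and CRIM1 (0.88). In the list of androgen receptor and luminal prostate markers, 3 of 7 fell (among them HOXB13 −1.64 and TMPRSS2 −0.74, camera adjusted p = 0.164). Of the FOXO targets, 4 of 13 fell (TXNIP −2.31, IRS2 −0.87, BNIP3L −0.70, BCL6 −0.49), and of the RAS-ERK output genes FOSL1 (−1.07) and DUSP6 (−0.93) fell while HBEGF (1.01) rose. Neither list passed (adjusted p = 0.606 and 0.468).

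A fit without 1 array leaves a lone array in its group and has less power. A lower count there does not show that the changes rest on the array left out. In this comparison the number of changed genes was lower without each of its arrays. It was 7 without control replicate 1, 10 without control replicate 2, 77 without DAB2IP siRNA replicate 1 and 266 without DAB2IP siRNA replicate 2. With median centring alone, which leaves the shapes of the intensity distributions as they are, it was 3905 with 573 higher (14.7%, against 41.1% of the 1777).

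The comparison of the miR-149-3p mimic with control asks what the mimic does in the same cells. The control is an siRNA and the series holds no control mimic, so effects of transfecting any mimic are not separated from those of the microRNA. The lipase inhibitor gene ANGPTL4 rose most (log2 fold change 3.45, SE 0.293, limma adjusted p = 0.00155), followed by the hair keratin KRT86 (3.27, SE 0.179, adjusted p = 8.91e-04) and the hypoxia-inducible ANKRD37 (3.02, SE 0.13, adjusted p = 8.91e-04). The glucose-6-phosphatase gene G6PC3 fell most (−3.01, SE 0.135, adjusted p = 8.91e-04), followed by the keratin KRT75 (−2.96) and GPRIN1 (−2.94, above background on 1 of 2 mimic arrays). Other large rises were those of MAP7D2 (3.02), the cortisol-regenerating enzyme HSD11B1 (2.51), the chemokine receptor ACKR3 (2.50), the GTPase RHOV (2.44), CALHM3 (2.34), the oxytocin receptor OXTR (2.26), DEPP1 (2.21) and SETSIP (2.20), a gene similar to SET. The synaptotagmin gene SYT12, not above background in the control, was at least 4.79-fold higher (adjusted p = 0.00225). Other large falls were those of IGFBP5 (−2.79), CERCAM (−2.71), the selenoprotein SELENON (−2.68), the transcription factors NFIC (−2.63) and FOXM1 (−2.59), smooth muscle actin ACTG2 (−2.55) and ARHGDIA (−2.47). FAM200C was at least 6.04-fold lower (adjusted p = 8.91e-04) and, on its tested probe, the myosin light chain MYL9 at least 5.99-fold lower (adjusted p = 9.36e-04). In all, 4905 of 15767 genes changed (2280 higher and 2625 lower, 31.1%), of which 519 rose and 897 fell by at least 2-fold.

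Cell division genes fell with the mimic. Of the mitosis genes, 18 of 20 fell and 0 rose, with the same counts adjusted over the list alone, among them the kinetochore motor CENPE (−1.44), the kinesins KIF20A (−1.44) and KIF11 (−1.40), and CENPF (−1.34). Camera gave an adjusted p of 1.27e-07 (adjusted p = 0.244 with an estimated correlation). Of the G1/S and DNA replication genes, 14 of 22 fell and 0 rose (14 and 1 adjusted over the list alone), including E2F2 (−1.53), MCM10 (−1.42), the helicase subunit MCM3 (−1.26) and GINS2 (−1.18). For the list, the camera adjusted p was 1.96e-05 (adjusted p = 0.379 with an estimated correlation).

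Hypoxia and glycolysis genes rose with the mimic, 14 of 20 with 0 lower (16 and 0 adjusted over the list alone). ANKRD37 (3.02), the prolyl hydroxylase EGLN3 (2.04), the glucose transporter SLC2A1 (1.70) and the enolase ENO2 (1.34) were the largest. Against all other genes, camera gave adjusted p = 4.5e-07 (adjusted p = 0.379 with an estimated correlation). NF-kB and inflammatory targets also rose, 13 of 24 with IL32 (−0.57) lower (15 and 1 adjusted over the list alone), led by the cytokine genes CSF2 (2.10), CCL20 (1.98) and LTB (1.5) and by TNFAIP3 (1.10). The camera adjusted p was 1.45e-04 (adjusted p = 0.244 with an estimated correlation). The interferon-stimulated genes went down, 10 of 21 with ISG20 (0.53) higher (12 and 2 adjusted over the list alone), among them the antiviral genes OAS2 (−1.69), OAS3 (−1.46) and IFIT1 (−1.20) and the RNA sensor gene RIGI (−1.08). Camera gave an adjusted p of 0.00198 (adjusted p = 0.564 with an estimated correlation).

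Stress lists rose with the mimic too. Of the ATF4 and amino acid response genes, 7 of 16 rose (9 adjusted over the list alone), led by the lipoprotein receptor VLDLR (2.17), DDIT4 (1.72), SLC7A11 (1.5) and the serine synthesis enzyme PSAT1 (1.26). The amino acid transporter SLC7A5 fell (−1.13). For the list, the camera adjusted p was 0.00126 (adjusted p = 0.626 with an estimated correlation). Of the ER chaperones, 5 of 13 rose and 1 fell (6 and 1 adjusted over the list alone), with HERPUD1 (1.59), CANX (1.17), DNAJC3 (0.87) and HSPA5 (0.82) higher and CALR (−0.80) lower (camera adjusted p = 0.0192, adjusted p = 0.641 with an estimated correlation). Of the NRF2 targets, 8 of 13 rose and 1 fell (10 and 1 adjusted over the list alone), with SLC7A11 (1.5), OSGIN1 (0.93) and the antioxidant enzyme SRXN1 (0.92) higher. Against all other genes, camera gave adjusted p = 0.00358 (adjusted p = 0.544 with an estimated correlation).

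Epithelial genes rose with the mimic, 9 of 16 with 0 lower, and the same counts adjusted over the list alone. The tight junction gene OCLN was at least 2.7-fold higher (adjusted p = 0.00643), and the transcription factor ELF3 (1.04) and the claudins CLDN4 (0.89) and CLDN7 (0.78) rose. The camera adjusted p was 0.00189 (adjusted p = 0.379 with an estimated correlation). The median of this list turned to −0.04 under median centring, where the median of all genes was −0.34. Of the TGF-beta and SMAD targets, 6 of 13 rose and 1 fell (9 and 1 adjusted over the list alone), with SMAD7 (1.26), SKIL (0.74), ID1 (0.71) and TGIF1 (0.70) higher. Camera gave an adjusted p of 0.0192 (adjusted p = 0.379 with an estimated correlation). That call was lost under median centring (adjusted p = 0.0514, from 0.00486 over the alternatives), where the list median was −0.02. Outside the lists that passed, the matrix protease MMP9 (2.16), the urokinase receptor PLAUR (1.28) and the collagen crosslinker LOX (2.15) rose, and the microRNA processing nuclease DROSHA fell (−1.38). TIMP2 fell by 1.56 on its tested probe, and its other detected probe had the opposite sign. Of the 3 tested genes in the list of reported miR-149-3p targets, DAB2IP and AKT1 (−0.55, the same sign on 1 of its 2 other detected probes) fell, and E2F1 had a value of −0.33 (adjusted p = 0.502).

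Without control replicate 1, control replicate 2 or mimic replicate 1, the number of changed genes was 2297, 2179 or 3146. With median centring alone it was 8603 with 630 higher (7.3%, against 46.5% of the 4905). The mean unnormalized intensity was 1488 and 1247 on the control arrays, 1174 and 1193 on the DAB2IP siRNA arrays, and 1016 and 1074 on the mimic arrays.

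Lists that track RNA quality and other cell types were tested alongside. Of the cytosolic ribosomal protein genes, 0 of 25 passed limma's test with either treatment (RPL13 had the largest value with the siRNA, 0.44, adjusted p = 0.08). Their camera adjusted p was 0.0977 with the siRNA and 0.943 with the mimic, and fry adjusted p 0.0335 and 0.358. Of the respiratory chain genes, 1 of 17 rose with each treatment (COX5B 0.54 with the siRNA, SDHC 0.52 with the mimic), with camera adjusted p = 0.271 and 0.495 and fry adjusted p = 0.0335 and 0.0512. Of the leukocyte markers, 1 of 6 fell with each (CORO1A −0.80 with the siRNA, LCP1 −0.44 with the mimic). Of the 2 tested fibroblast markers neither passed with either treatment (LUM 0.57 and COL1A1 0.12 with the siRNA, adjusted p = 0.0609 and 0.557, and LUM −0.26 and COL1A1 0.26 with the mimic, adjusted p = 0.23 and 0.161). The 2 tested endothelial markers gave PECAM1 lower with the siRNA (−0.81) and ESAM higher with the mimic (1.10). The neuroendocrine marker ENO2, which is also on the hypoxia list, fell with the siRNA (−0.67) and rose with the mimic (1.34), and INSM1 was at least 1.49-fold lower with the mimic (adjusted p = 0.044). The median of the luminal markers was −0.50 with the siRNA, where 3 of 7 fell (camera adjusted p = 0.164, fry 0.0335), and 0.13 with the mimic, where 2 of 7 rose, among them TMPRSS2 (1.30; camera adjusted p = 0.435, fry 0.0498). Between the treatments it was 0.75, with 4 of 7 higher and 1 lower with the mimic (camera adjusted p = 0.281, fry 0.00598). Of the immediate early genes, 2 of 11 rose with the siRNA (ATF3 1.31, KLF2 0.93) and 4 of 11 with the mimic (KLF4 0.96, IER2 0.85, ZFP36 0.80, JUN 0.60), with medians of 0.22 and 0.53 and camera adjusted p = 0.143 and 0.0744.

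**Figure D2:**
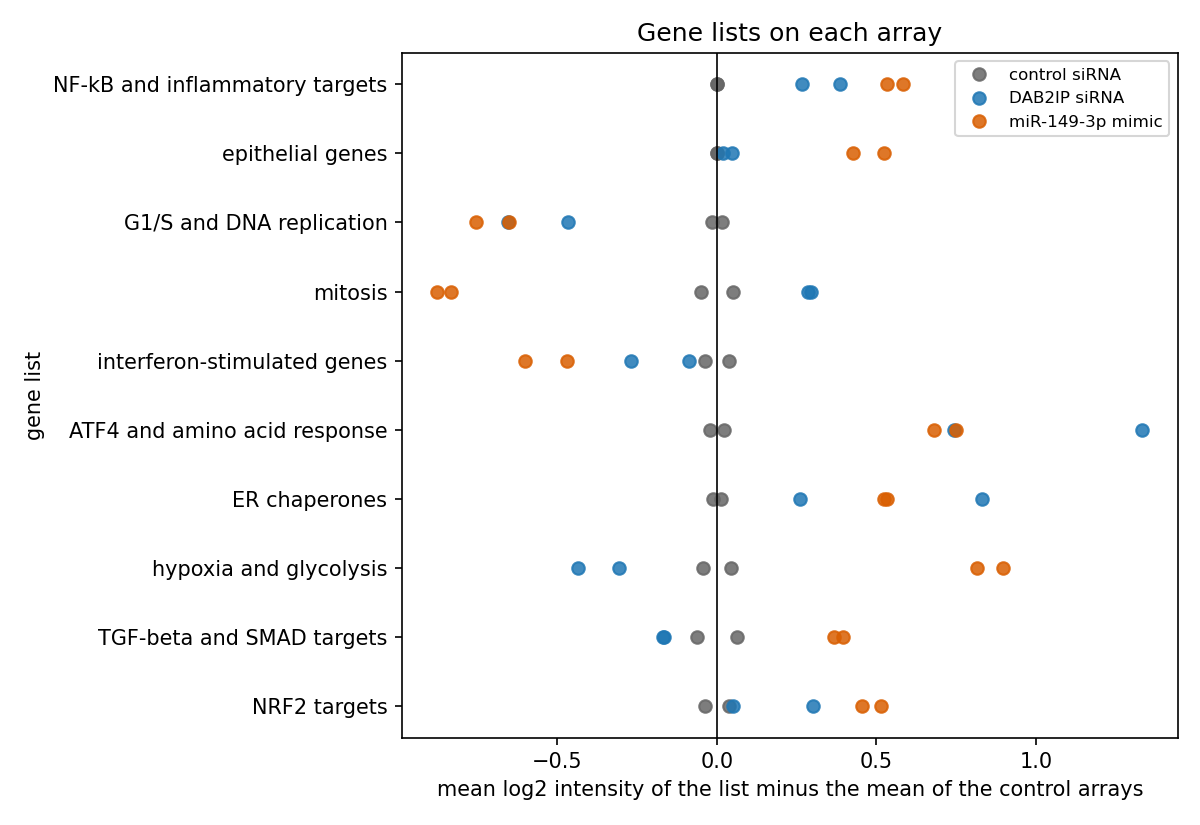
Mean log2 intensity of the tested genes of each list, minus the mean of the control arrays (horizontal axis), for the 10 lists that passed in any comparison, with 1 point per array and the colours giving the group. The hypoxia and glycolysis list lies at 0.82 and 0.90 on the mimic arrays and at −0.44 and −0.31 on the DAB2IP siRNA arrays.

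The comparison of the mimic with the DAB2IP siRNA tests the difference between the 2 treatments itself. Control levels are not subtracted in it, though the control arrays enter the normalization and the variance. Mitosis genes were lower with the mimic (19 of 20, 0 higher), led by CENPF (−1.84), CENPE (−1.76), CCNB1 (−1.73) and KIF20A (−1.69). Hypoxia and glycolysis genes were higher (16 of 20, 0 lower), led by ANKRD37 (3.74), ENO2 (2.00), EGLN3 (1.9) and PFKFB4 (1.86). These counts were the same adjusted over the list alone, and the camera adjusted p was 1.49e-09 and 3.66e-09 (adjusted p = 0.345 and 0.459 with an estimated correlation). Of the TGF-beta and SMAD targets, 6 of 13 were higher and 1 was lower, also adjusted over the list alone, with PMEPA1 (2.23), ID1 (1.79) and SMAD7 (0.99) higher. Of the epithelial genes, 7 of 16 were higher and 1 was lower (9 and 1 adjusted over the list alone), with ELF3 (1.65), KRT19 (0.89), ST14 (0.77) and KRT8 (0.74) higher. Both had a camera adjusted p of 0.0112 (adjusted p = 0.459 with an estimated correlation). The ATF4 list did not pass (adjusted p = 0.528), though SESN2 (−2.13), DDIT3 (−1.68) and CHAC1 (−1.46) were lower with the mimic and VLDLR (2.41) was higher. The largest single differences were ANGPTL4 (4.38), IL11 (4.01), ACKR3 (3.86), ANKRD37 (3.74), DEPP1 (3.17) and KRT86 (3.09), higher with the mimic, and ERVMER34-1 (−3.12), the interferon-induced chemokine CXCL10 (−3.10), G6PC3 (−2.90) and ACTG2 (−2.81), lower with it. The relaxin gene RLN2 and FAM200C were at least 4.35-fold and 5.67-fold lower. In all, 5746 genes differed (2701 higher and 3045 lower with the mimic, 36.4%), 853 and 903 of them by at least 2-fold. The number was 3601 and 3611 without DAB2IP siRNA replicate 1 and 2, and 5044 and 4991 without control replicate 1 and 2. With median centring alone it was 7132 with 1421 higher (19.9%, against 47.0%).

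To ask how far the 2 treatments act alike, their fold changes against the shared controls were set side by side. A group of genes moved strongly in both. GIPC1 (−2.38 with the siRNA, −2.08 with the mimic), the RNA-binding protein gene RALY (−1.88 and −2.47), the neuropeptide gene NPY (−1.88 and −1.92), HIPK2 (−2.08 and −1.78), KRTAP3-1 (−1.80 and −2.27, the latter above background on 1 of 2 arrays) and the aquaporin AQP12B (−1.62 and −1.84) fell with both. CFDP1 (2.21 and 1.98), CLDN1 (2.88 and 1.85) and LURAP1L (1.98 and 1.72) rose with both. Other genes moved apart, and these were chosen after their values were seen: CXCL10 (1.67 with the siRNA, −1.43 with the mimic), PDE1C (1.44 and −1.23) and ERVMER34-1 (1.76 and −1.36) rose with the siRNA and fell with the mimic, while ACKR3 (−1.36 and 2.50), DPYSL2 (−1.20 and 1.15) and LEMD1 (−1.14 and 1.23) did the reverse.

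Of the 886 genes called in both comparisons, 664 went the same way (74.9%). Among these, 501 did not pass the test between the treatments, which does not show that the changes were equal. On simulated data that test called 4.5% of differences of 0.5 log2 units and 67.2% of differences of 1. The 287 genes higher in both and 377 lower in both compare with 105.6 and 174.3 for independent lists. The 71 higher with the siRNA and lower with the mimic compare with 121.5, and the 151 of the reverse kind with 151.4. Across the 15767 genes, which are not independent replicates, the fold changes had Pearson r = 0.258 and a Spearman correlation of 0.236, and 57.6% had the same sign. Simulated unchanged groups gave a mean r of 0.50 and 66.7% with the same sign through the shared controls alone. Both measures also depend on how much each treatment changes genes, which the simulation leaves out. They therefore set no reference for the measured r and share. The covariance was 0.0688 against 0.0177 simulated, a difference of 0.0511. In a split chosen after the data were seen, each treatment was set against a different control array. The fold changes then had r = 0.147 (siRNA against control 1, mimic against control 2) and 0.199 (the reverse), against 0.322 and 0.291 with control 1 or control 2 for both treatments. Against a single control array, with the normalization over all 6 arrays kept, 0 genes passed limma with the siRNA at the adjusted threshold (7 and 10 in the fits that normalize 5 arrays anew), so the split gives no shared calls. At an unadjusted p under 0.05, 3825 and 3272 genes passed with the siRNA, and 1019 and 1034 genes passed with both treatments in the same direction (653.3 and 578.6 for independent lists), with 612 and 480 in opposite directions (646.2 and 570.1). These fits share the treated arrays in their variance, and a level that both control arrays share stays in them. The count of 664 was 4 and 5 without control replicate 1 and 2, and 39 and 117 without DAB2IP siRNA replicate 1 and 2. With median centring alone it was 2413, of which 95 were higher.

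**Figure D3:**
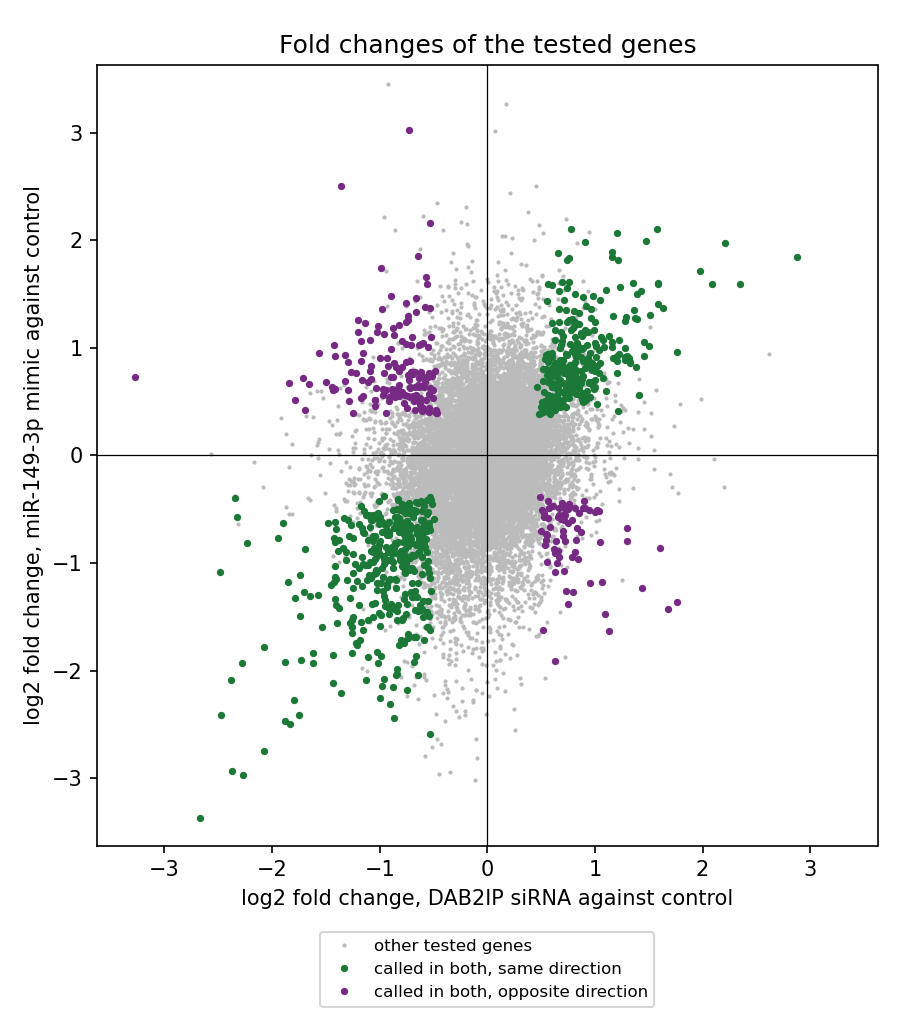
Log2 fold change of each of the 15767 tested genes for DAB2IP siRNA against control (horizontal axis) and miR-149-3p mimic against control (vertical axis). Coloured points are the 886 genes called in both comparisons, 664 in the same direction and 222 in opposite directions.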

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

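Probes without a gene name took no part in the comparisons, and some of them changed. Of 1009 such probes that were detected, 9 changed with the DAB2IP siRNA (2 higher and 7 lower, 0.9%), and 36 with the mimic (11 higher and 25 lower, 3.6%), both against control. Between mimic and DAB2IP siRNA, 86 differed (52 higher and 34 lower with the mimic, 8.5%). The limma calls used an adjusted p under 0.05 over these probes, and what the probes measure was not analysed here.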

How the results depend on the processing

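Under the other normalizations and the offset of 50, 0 called genes were called with the opposite sign. All kept their sign except with median centring, where 4566 of the 4905 mimic calls did, and where the medians of the epithelial and TGF-beta lists with the mimic fell below 0 (−0.04 and −0.02). How many genes passed depended on the choices. For DAB2IP siRNA against control, 1777 genes became 2952 with the cubic spline table, 3366 with quantile normalization without background correction, 3352 with the series matrix, 3905 with median centring (573 higher and 3332 lower, 14.7% higher against 41.1%), 506 without a filter on detection (31.2% higher), 2924 with detection p under 0.01 on all 6 arrays, 3669 with trend and robust, and 137 at an adjusted p under 0.01 (24.1% higher). For mimic against control, 4905 became 8603 with median centring (630 and 7973, 7.3% against 46.5%), 3039 without the filter and 1953 at an adjusted p under 0.01. For mimic against siRNA, 5746 became 2719 at an adjusted p under 0.01, and 7132 with median centring (1421 and 5711, 19.9% against 47.0%). The 664 genes called in both in the same direction became 1041, 1209, 1203 and 2413 under the 4 other normalizations in the same order, 187 without the filter, 1048 with the stricter detection, 1318 with trend and robust, and 47 at an adjusted p under 0.01. Unfiltered tests hold more genes, 30471; the cause of the other moves was not tested. Under median centring the median of all genes was −0.126 for the siRNA, −0.34 for the mimic and −0.198 between them, so its values are read relative to that. Of the calls, 1516 to 1749 of 1777, 3198 to 4817 of 4905 and 4323 to 5655 of 5746 were also called with the same sign under the other normalizations and the offset of 50, fewest under median centring.

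DAB2IP with the siRNA lost its call without the filter (−1.23, adjusted p = 0.0653, with 0.00292 to 0.142 over all alternatives), and stricter detection on all arrays gave no DAB2IP value. The correlation of fold changes was 0.313 with median centring, 0.288 without the filter and 0.28 with every probe on its own, against 0.258. With separate control arrays for the 2 treatments, chosen after the data were seen, it was 0.147 and 0.199, and 0 genes were shared at the adjusted threshold in limma (1019 and 1034 at an unadjusted p under 0.05), since 0 passed with the siRNA against 1 control array. The 6 lists that shifted with the siRNA became 11 without the filter and 14 with fry. With an estimated correlation, 0 lists passed camera for the siRNA and 0 for the mimic (10 at the preset), with 1 and 2 at an unadjusted p under 0.05, while fry called 14 and 13.

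Leaving out 1 array gave 7 to 1542 genes for the siRNA, 2179 to 4457 for the mimic, 3601 to 5044 between them and 4 to 478 shared, with fewest without a control array (without an siRNA array for the comparison between treatments). DAB2IP moved from −1.489 to −0.961 with the siRNA and from −1.291 to −0.777 with the mimic, the correlation from 0.239 to 0.322, and the shifted lists from 5 to 9 with the siRNA and 10 to 10 with the mimic. These fits have fewer samples and assume that the lone sample of a group varies like the others. Over the 6 such fits, values of named genes kept their call in 1494 of 2040 cases. Without the filter, 264 of 340 did, under median centring 302, and under the 4 other changes of normalization or offset 339 or 340.

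Deviations from the group means correlated at 0.057, 0.004 and 0.068 between arrays with the same replicate number. An effect of that number shared by the groups was therefore small. Whether the samples are paired cannot be told from these values, and the labels do not say. With the number as a block, 1476, 4671 and 5584 genes passed in the 3 comparisons and 579 were shared. DAB2IP was called with both treatments, and 6 and 10 lists passed. The slide as a block and the site test over untranslated regions were not run.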

Other observations

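Gene families were picked by symbol after the fold changes were seen (14 families, camera adjusted over the 14). Their p-values come from the same fold changes, so they describe the families and are no separate support. Some members are also on the gene lists. The minimum of 5 tested genes was not applied here, and the sodium channel family has 4. With the DAB2IP siRNA, subunits of the epithelial sodium channel fell (3 of 4, adjusted p = 0.0011, lost with an estimated correlation, 0.268): SCNN1A (−1.57), SCNN1B (−1.42) and SCNN1G (−1.94). Subunits of the V-ATPase, the proton pump of lysosomes and other acidic compartments, fell in 5 of 21 cases with 0 higher (adjusted p = 0.00856, lost with an estimated correlation, 0.268), led by ATP6V1B2 (−1.47) and ATP6V0E2 (−0.99). Integrins fell in 4 of 21 cases with 0 higher (adjusted p = 0.0362, lost with an estimated correlation, 0.537), led by the epithelial ITGB4 (−1.32) and ITGB6 (−1.32). Chemokines rose in 5 of 17 cases with 0 lower (adjusted p = 0.0362, lost with an estimated correlation, 0.332), among them CXCL10 (1.67), CCL3L3 (1.55), CXCL2 (1.19) and CCL5 (0.96). Under median centring the 4 family medians were −1.244, −0.331, −0.234 and 0.125 in the order above, with a median of −0.126 over all genes. A sign below 0 is a weak check there, since the median of all genes was below 0 too. The integrins lay nearer to all genes than with neqc, where their median was −0.313 against 0.006.

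With the mimic, kinesins fell (14 of 27, with KIF5B and KIF5C higher, adjusted p = 0.0203, lost with an estimated correlation, 0.474), among them KIF18A (−1.79), KIF24 (−1.76) and KIF20B (−1.55), beside the kinesins of the mitosis list. Histone genes rose (17 of 49, 5 lower, adjusted p = 0.00671, lost with an estimated correlation, 0.474), led by H2BC5 (1.81), H4C8 (1.42) and H4C14 (1.34). Many histone genes are near copies of each other, so single members are uncertain. Proteasome subunits rose in 4 of 37 cases with 0 lower (adjusted p = 0.0203, lost with an estimated correlation, 0.474), led by PSMC4 (1.04) and PSMD7 (0.62). Under median centring, with a median of −0.34 over all genes, the medians of the histone genes (−0.04) and proteasome subunits (−0.26) turned below 0. None of the HOX genes, keratins, ZNF genes, collagens, claudins, serpins and TRAPP subunits passed as a family with either treatment (smallest adjusted p 0.156 with the siRNA and 0.191 with the mimic).

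The lists not yet described did not pass camera with either treatment. A list adjusted p in what follows is the camera value of the whole list, not of the genes named beside it. Of the mesenchymal genes, 2 of 12 fell with the siRNA (S100A4 −0.88, TNC −0.65), with a list adjusted p = 0.99. With the mimic 2 rose (LOX, S100A4 1.18) and 4 fell (list adjusted p = 0.921). Of the Wnt targets, the siRNA lowered TCF7 (−1.45) and CD44 (−1.32) and raised MYC (0.65), with a list adjusted p = 0.547. The mimic lowered TCF7 (−1.20) and raised AXIN2 (0.73), with a list adjusted p = 0.541. The p53 targets GDF15 (1.43) and FAS (0.82) rose with the siRNA (list adjusted p = 0.0977). With the mimic GDF15 (1.52) rose and FAS (−0.48) fell (list adjusted p = 0.921). In the BCL2 family, MCL1 (0.82) rose while BMF (−1.42) and BCL2L1 (−0.89) fell with the siRNA (list adjusted p = 0.65). With the mimic 5 of 16 rose and 3 fell, with BID (1.32), MCL1 (1.22) and BIK (1.10) higher (list adjusted p = 0.264). Of the cholesterol synthesis genes, LSS (−0.74) fell and SQLE (0.55) rose with the siRNA (list adjusted p = 0.143). With the mimic 3 rose and 2 fell of 20 (list adjusted p = 0.495). Of the extracellular proteases and their inhibitors, 1 rose and 2 fell of 15 with the siRNA, among the latter SERPINE2 (−1.17). With the mimic 5 rose and 3 fell. The list adjusted p was 0.478 and 0.636. In the RasGAP family, 1 of 8 rose with the siRNA (RASA2 1.33) and 3 rose with the mimic (RASA3 0.94, RASA2 0.87, RASAL3 0.86), while DAB2IP fell with both. The camera adjusted p was 0.727 and 0.495. Of the small RNA machinery, 1 rose and 2 fell of 11 with each treatment, and DROSHA (−0.75) was among those that fell with the siRNA. The list adjusted p was 0.164 and 0.824. Of the heat shock genes, BAG3 (−0.86) fell with the siRNA (list adjusted p = 0.468). With the mimic 0 of 10 passed (list adjusted p = 0.921). There HSPA1B was at 0.82 (limma adjusted p = 0.0632) and its near-identical copy HSPA1A at 0.65. With the mimic, 3 of the 17 RAS-ERK output genes rose and 4 fell, among the latter ETV4 (−1.49; limma adjusted p = 0.00125). Of the 13 FOXO targets 5 rose, among them CDKN1B (1.20; limma adjusted p = 0.00216), and 1 fell. Of the 12 YAP targets 3 rose and 2 fell, among the latter AXL (−1.37; limma adjusted p = 0.00285). The list adjusted p was 0.962, 0.0753 and 0.242.

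Genes whose 50-base probe holds CCCTCCC, the site that would pair with bases 2 to 8 of miR-149-3p, were lower with the mimic. Over 153 genes the median log2 fold change lay −0.278 from that of the other 15614, and 56 fell and 20 rose. The one-sided permutation p was 1e-05, the smallest that 100000 resamples can give. These resamples treat genes as independent and draw from probes of any composition. The 6 other orders of the same bases gave −0.187 to 0.008, with no p computed. Under the other normalizations and the offset of 50 the difference was −0.253 to −0.157, smallest with median centring. A trend on the C and G shares of the probe as the whole cause is argued against, since the difference was −0.287 after it was removed. Other features of C-rich stretches stay open, since the 6 other orders still gave −0.167 to 0.014 after that step. An effect of any transfected small RNA, or of the shared controls, stays open: the siRNA comparison gave −0.103 (permutation p = 0.0048, other orders −0.168 to −0.018), 37.1% of the difference with the mimic and 51% with median centring, where it was −0.08, and the mimic against the siRNA, where control levels are not subtracted, gave −0.038 (permutation p = 0.236, other orders −0.18 to 0.224). The longer site CCCTCCCA, in 50 of these genes, gave −0.265 for mimic against control and −0.006 for mimic against siRNA, no larger than CCCTCCC. Pairing with the seed may contribute and is not separated from the other causes by the tests. Those of pairing and of an effect of any small RNA were completed after their results were seen.

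The hypoxia and glycolysis list moved in opposite directions under the 2 treatments, and a difference in how the 2 small RNAs act on this group is a hypothesis. The normalization as its cause is argued against: over 4 other normalizations the list median lay between 0.241 and 0.696 with the mimic and between −0.458 and −0.276 with the siRNA (smallest size 0.241). The 4 are not all separate checks, since quantile normalization and the series matrix gave nearly the same number of calls (3366 and 3352 with the siRNA). A single array is argued against too, since at least 62.9% of each median was kept when any 1 array was left out. Density or medium of the cultures, which could also move these genes, is not given in the labels and stays open.

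The ATF4 and amino acid response list was higher with the DAB2IP siRNA, more on replicate 1 (mean shift 1.33) than on replicate 2 (0.745), and by 0.751 and 0.681 on the mimic arrays. A single array as the cause is argued against, since at least 63.9% of the median was kept when any 1 array was left out (lowest median 0.683, without DAB2IP siRNA replicate 1). A low level in both control arrays stays open: they differed by 0.044 (4.2% of the shift of 1.04), which was set in advance to exclude it, but 2 arrays that may come from 1 culture can be low together. The strong estimated correlation within the list (0.525) stays open too, so a link to the loss of DAB2IP is a hypothesis that may not hold in other cultures.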
